A study of Drosophila melanogaster with 2 samples.

How the data were processed

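The data were peak lists from ChIP-seq of E2f2-eGFP in whole embryos aged 0 to 24 h, from 2 biological replicates. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the precipitation used an antibody against GFP on transgenic flies. The labels put both samples in 1 group, so both were analysed as replicates of that group and no groups were compared. The aligner, the peak caller, their versions and the read depth are not given in the sources used here.

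Each replicate had a ranked and a thresholded peak list, and the series had 2 of each made from both replicates, per the file records deposited with the samples. IDR, the irreproducible discovery rate, measures how poorly a peak's rank holds between 2 rankings. The records do not state what was ranked against what within a single replicate. Per those deposited records, ranked lists were derived from the alignments and a control file, and thresholded lists from these and a further input file that the records do not describe. The signal value of a peak was computed by the authors' peak caller, per the layout of the deposited files, and what it is relative to is not given in the sources used here. It was used to describe, rank, split and compare peaks within a list, by permutation tests where stated, and its ranks were correlated between the lists of the 2 replicates. The deposited score is a whole number from the IDR step, and every thresholded peak had a score of at least 830. The −log10 of the global IDR was read from the deposited ranked lists: every thresholded entry had a value of at least 2 (an IDR of at most 0.01) in its ranked list. Further per-replicate columns of the series' ranked lists carry no names and were not used. Peaks are not independent replicates, and tests over peaks or genes describe these lists.

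The conservative thresholded list of the series was the main list. Its 7312 entries include 398 that repeat the interval of another entry with another summit. Coordinates are those of dm6, which the labels name, and are given counted from 1. Chromosome lengths and the last peak of each chromosome were checked against a Release 6 reference genome, and every peak lay within the lengths. Genes and TSSs came from the Ensembl annotation of that assembly (13968 protein-coding genes on the chromosome arms), and sequence from the RefSeq copy of the assembly.

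A gene was bound when a main-list summit lay within 500 bp of any of its annotated TSSs. Shares have exact Clopper-Pearson 95% intervals and odds ratios have Woolf 95% intervals, with 0.5 added to each cell of a table that holds a 0. Overlaps of replicates were compared with 1000 shuffles within chromosomes, and the share of summits at TSSs with 1000 sets of random positions. Candidates are ranked entries below the IDR threshold; the backgrounds of genes with a ranked entry also include genes bound in the main list. Gene lists were tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over 18 lists. The names nos, rye and calypso matched no gene of the annotation and were left out. The ribosomal protein list was built from symbols and includes related genes such as RpL7-like. Motifs were searched on both strands within 100 bp of each summit and of a point 500 bp to a side drawn at random, and compared with exact McNemar tests adjusted over 8 motifs. Signal values with and without the motif were compared with 100000 permutations. A summit's annotation was taken in the order 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic.

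The lists, motifs, tests, windows and most alternatives were fixed before the data were examined, as was the rule for named genes: the gene nearest each of the 20 peaks of highest signal value with a TSS within 500 bp, every E2F, RB and dREAM gene, up to 4 bound genes of highest signal value and up to 2 unbound genes of each other list, and E2f2. Some genes that this rule picks are not reported here. Other genes named with a motif sequence, a divergent neighbour, or as peaks away from a TSS were picked from among these or after their values were seen. The alternatives were the larger thresholded list, the 1000 strongest peaks, the separate list of each replicate, peak midpoints, TSS windows of 250 and 1000 bp, gene 5′ ends, other backgrounds, other motif windows and forms, and other overlap rules. Alternatives chosen after seeing the data were a single entry per merged region, the return of absent entries to the main list, a background of genes with a stronger ranked entry, and the assignment of each peak to its nearest TSS.

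The list test was tested on simulated binding of the 13968 genes over 50 draws, with planted lists bound at 70% against 30%: it recovered 91.0% of the planted lists and called 2.17% of the others. Each gene was drawn on its own, whereas in the data 40.7% of genes were bound and neighbouring genes can share a peak. These rates may therefore not carry over to the data. With the E2F motif planted in 29.9% of windows of random sequence with equal base frequencies, the motif test recovered an excess of 29.4 points and called 0 other motifs. Summits and flanks had the same composition there, so this does not show how the test behaves where promoter composition differs. Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. A control sample, signal tracks and alignments were not used here.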

Results

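Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the transcription factor E2f2 sits on the genome of whole Drosophila melanogaster embryos collected from 0 to 24 h of development. E2f2 is the fly E2F family member that acts mainly as a repressor, together with the partner Dp, the retinoblastoma family proteins Rbf and Rbf2 and the dREAM complex. The flies carried E2f2 fused to eGFP, and the fusion protein was precipitated with an antibody against GFP. The 2 samples were biological replicates of this single group, so no contrast between conditions was possible, and no untagged or input sample was analysed here. The question was which promoters and gene groups carried E2f2 peaks in each replicate and in the list made from both. Replicate 1 had 5002 thresholded peaks and replicate 2 had 8250. The conservative list made from both replicates held 7312 peaks covering 2845 kb in 6315 merged regions, with a median peak width of 510 bp, and is called the main list. Read depth was not given in the sources used here, so intervals cover counting error over peaks or genes only.

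Both replicates placed E2f2 at largely the same promoters, and replicate 2 had more sites. Of the peaks of replicate 1, 4750 of 5002 (exact 95% interval 94.3% to 95.6%) overlapped a peak of replicate 2 by at least 1 bp, against a mean of 4.36% and a highest value of 5.38% in 1000 shuffles (p = 0.001, the smallest these shuffles can give). In the other direction 5096 of 8250 peaks (61.8%, 60.7 to 62.8) were shared. At the level of genes, 4680 protein-coding genes were bound in replicate 1 and 5884 in replicate 2. Of these 4497 were bound in both, which is 96.1% of those of replicate 1 and 76.4% of those of replicate 2. The main list was not limited to peaks found in both separate lists. Of its 7312 peaks, 5031 (68.8%) overlapped a thresholded peak of each replicate. Of the 5681 genes bound in the main list, 4442 were bound in both replicates. The cell cycle genes CycA, mad2, CycE and PolE1, and E2f2 itself, were bound in both replicates. Ranked entries of both replicates, with thresholded entries included, were merged into regions. Across the 26722 regions ranked in both replicates, passing in 1 replicate went with passing in the other (odds ratio 167, 95% interval 144 to 194, Fisher's exact test). Over the 4750 shared peaks the signal values had a Spearman's rho of 0.809, a description across peaks, which are not independent replicates. The shared percentage depended on the overlap that was required: with 50% reciprocal overlap it was 77.8% for replicate 1 and 50.9% for replicate 2.

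E2f2 peaks lay mostly at the starts of genes. In the main list 5148 of 7312 summits (70.4%, 69.3 to 71.4) were within 500 bp of an annotated transcription start site (TSS) of a protein-coding gene, with a median distance of 78 bp among these. Of the 73049 ranked candidate peaks that did not pass the threshold, 14.4% were that close (odds ratio 14.2, 13.4 to 14.9, Fisher's exact test, two-sided), and shuffled positions gave a mean of 11.5% (highest 12.9%). By annotation, 49.4% of summits were intergenic, 27.9% intronic and 15.9% in a 5′ UTR. Coding exons held 2.69% of the summits against 25.4% of the candidates.

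The 20 strongest promoter peaks stood at genes of varied function, and no test of a common theme was run. The highest signal value of the list belonged to an intergenic peak on chromosome 2L from 16487471 to 16488063 (dm6), with its summit 384 bp from a TSS of Nepl8, a neprilysin-like gene. Next among peaks with a TSS within 500 bp were CG9630 (signal value 3310), mad2 (3247), a spindle checkpoint gene, r-l (3106), which encodes the last enzyme of pyrimidine synthesis, and jar (3102), the gene of myosin VI. CycA, the gene of cyclin A, had a signal value of 2871 in an intergenic peak on 3L from 11833241 to 11833891, 33 bp from its TSS. Cks30A, a partner of the mitotic kinase Cdk1, had 2571. The metabolic genes Gpdh1 (2663), Idh (2465) and CD98hc (2633), an amino acid transporter subunit, and the nuclear receptor gene ftz-f1 (2486) were also among the 20. The rest were CG18278, vig, Plc21C, CG3407, CG33169, Sgt1, CG5114, CG4502 and CG10600, with values between 2464 and 3035. All 20 genes were bound in both replicates. Of their summit windows, 5 held an E2F motif. In the peaks of jar, Gpdh1 and CG10600 it read TTTGGCGC, starting at 24271394 on 3R, 5943587 on 2L and 18839830 on 2L.

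Genes for DNA replication, mitosis and DNA repair carried E2f2 peaks almost without exception. Of 41 DNA replication genes 40 were bound (97.6%, against 40.5% of other protein-coding genes; odds ratio 58.8, 8.08 to 428, exact adjusted p = 1.94e-14). Their highest signal values were those of PolE1 (1997) and PolE2 (1978), subunits of DNA polymerase epsilon, and of the origin licensing factors Cdc6 (1837) and dup (1517), the fly Cdt1. The PolE1 peak lay on 3R from 23347805 to 23348384 and the dup peak, in a 5′ UTR, on 2R from 15380383 to 15381079. The unbound member, PolD1, the catalytic subunit of DNA polymerase delta, was bound in the separate list of each replicate. Of 44 mitosis genes 42 were bound (95.5%, odds ratio 30.9, 7.47 to 128, exact adjusted p = 3.69e-14), among them CycB3 (2264), a mitotic cyclin, and borr (2129), a subunit of the chromosomal passenger complex. The unbound members were fzr, which was bound in the list of replicate 2, and Klp61F. All 29 DNA repair and checkpoint genes were bound (odds ratio 86.5, 5.28 to 1416, with 0.5 added to each cell, exact adjusted p = 1.15e-11), among them FANCI (2097) and Fancd2 (958), genes of the Fanconi anaemia pathway. In the separate list of each replicate 28 of the 29 were bound (odds ratio 55.9 in replicate 1 and 38.6 in replicate 2). No call of these 3 lists ended in 14 alternatives, but the odds ratios ranged from 7.64 to 106 for DNA replication, 11.9 to 59.5 for mitosis and 3.77 to 87.8 for DNA repair.

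Most genes of the E2F and dREAM machinery itself were also bound, 11 of 13 (84.6%, odds ratio 8.04, 1.78 to 36.3, exact adjusted p = 0.00480). The dREAM subunit mip120 had the highest signal value (1593), followed by Rbf (991) and E2f2 (968). The E2f2 peak lay in the 5′ UTR of its own gene on 2L, from 21155968 to 21156499, with the summit 3 bp from a TSS. This is the gene whose fusion the transgenic flies carried. A control sample was not used, so an effect of the transgene on this peak could not be assessed. Values were 820 at Rbf2, 776 at E2f1, the activating E2F, 566 at Dp, 449 at Caf1-55, 443 at mip40, 191 at l(3)mbt, 132 at mip130 and 74.0 at HDAC1. Myb was unbound in both replicates, lin-52 was bound in replicate 1 alone, and mip130 and HDAC1 were not bound in the list of replicate 2. With replicate 1's list the odds ratio was 23.9, and with replicate 2's list the call of this group ended (odds ratio 3.09, exact adjusted p = 0.0647), as it did against genes with a stronger ranked entry at their promoter (odds ratio 6.27, exact adjusted p = 0.103).

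G1 and S phase regulators (11 of 15 bound, odds ratio 4.02, 1.28 to 12.6, exact adjusted p = 0.0183) and nucleotide synthesis genes (12 of 16, odds ratio 4.38, 1.41 to 13.6, exact adjusted p = 0.0128) were bound more often than other genes too. CycE, the cyclin that drives S phase entry, had a signal value of 1339, Cks85A 842 and Skp2 816, and CycD and Cdk4 were unbound, though CycD was bound in the list of replicate 1 and Cdk4 in that of replicate 2. Beside r-l, bound nucleotide synthesis genes were Ts, the gene of thymidylate synthase (896), bur (827) and Ctps (756), while Gart was unbound in both replicates. Neither call held when the background was restricted to genes with any ranked entry at their promoter (odds ratio 2.03, exact adjusted p = 0.316, and odds ratio 2.21, exact adjusted p = 0.249), and of 14 alternatives the first call ended in 7 and the second in 3.

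Binding was not limited to cell cycle genes. Ribosomal protein genes were bound at 77 of 93 (82.8%, odds ratio 7.10, 4.14 to 12.2, exact adjusted p = 4.43e-16), with the highest signal values at RpS29 (2306), RpL30 (1808), the related gene RpL7-like (1653) and RpS19b (1358), while RpL10, bound in the list of replicate 2, and RpL10Aa were unbound. Oxidative phosphorylation genes were bound at 54 of 86 (62.8%, odds ratio 2.48, 1.60 to 3.84, exact adjusted p = 8.42e-05), led by ATPsynB (1704), COX4 (1135), ND-B12 (1088) and ND-B22 (1037), with ATPsynC and ATPsynCF6 unbound. Polycomb and trithorax genes followed at 16 of 22 (72.7%, odds ratio 3.90, 1.52 to 9.97, exact adjusted p = 0.00592), with esc (2044), jing (1390), Sce (1074) and ph-p (871) highest and Su(z)2, bound in the list of replicate 2, and pho unbound. Germline and piRNA genes were bound at 17 of 26 (65.4%, odds ratio 2.76, 1.23 to 6.20, exact adjusted p = 0.0183), led by shu (1834), a piRNA pathway gene, and bam (1449), the germ cell differentiation factor, then stil (1174) and bgcn (996), with aub and AGO3 unbound. The calls of the Polycomb and trithorax and the germline lists also ended against genes with a ranked entry (odds ratio 1.97, exact adjusted p = 0.249, and odds ratio 3.14 with 21 members left, exact adjusted p = 0.0680), and each ended in 4 of 14 alternatives. Without genes that have a divergent neighbour the germline call ended too (6 of 14 members bound, odds ratio 1.94, exact adjusted p = 0.264). With the nearest TSS only it also ended (odds ratio 2.23, exact adjusted p = 0.0737). The summits at stil and RpS19b lay 448 and 335 bp upstream of their own TSSs. Their oppositely oriented neighbours had TSSs 520 and 382 bp upstream, nearer to these summits. With replicate 1's list the odds ratio was 4.66 for ribosomal protein genes (65 of 93 bound) and 4.48 for germline genes. Among the 1000 strongest peaks alone, ribosomal protein and oxidative phosphorylation genes were no longer bound more often than others (odds ratio 1.42, exact adjusted p = 0.421, and odds ratio 1.21, exact adjusted p = 0.655).

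Chemosensory receptor, cuticle protein, segmentation and homeotic, and muscle structure genes were bound less often. Only 7 of 179 chemosensory receptor genes (3.91%, odds ratio 0.0582, 0.0273 to 0.124, exact adjusted p = 2.59e-29) and 3 of 120 cuticle protein genes (odds ratio 0.0369, 0.0117 to 0.116, exact adjusted p = 3.12e-22) carried a peak. The bound receptors of highest signal value were Ir60e (1662), Gr63a (1406), Gr5a (396) and Ir60b (86.2), and Gr10a and Gr10b were unbound. Only 2 of the 7 bound receptors were bound in both replicates: the Gr5a peak overlapped a peak of replicate 2 without a replicate 2 summit inside the TSS window, and Ir60b was bound in neither separate list. The bound cuticle genes were Lcp9 (1120) and the neighbours Lcp2 and Lcp3, which shared a peak of 321, with Ccp84Aa and Ccp84Ab unbound. The summits at Ir60e, Gr63a and Lcp9 lay 275, 234 and 435 bp upstream of their own TSSs. Oppositely oriented neighbours had TSSs 322, 297 and 489 bp upstream, nearer to these summits. Without genes that have a divergent neighbour, 1 of 157 receptor genes and 0 of 107 cuticle genes were bound. With each peak assigned to its nearest TSS alone, 2 of 179 and 1 of 120 were. Over 14 alternatives the odds ratio ranged from 0.0162 to 0.200 for chemosensory receptors (0.0307 with replicate 2's list) and from 0.0118 to 0.0983 for cuticle proteins (0.0589 with that list), and no call ended. Segmentation and homeotic genes were bound at 5 of 34 (14.7%, odds ratio 0.251, 0.0970 to 0.648, exact adjusted p = 0.00290): bcd (378), sog (268), Scr (258) and hry (84.1) were the highest, and the gap genes hb and Kr were unbound. Muscle structure genes were bound at 3 of 21 (14.3%, odds ratio 0.243, 0.0715 to 0.824, exact adjusted p = 0.0183), namely Tm1 (858), Mef2 (780) and sls (257), with Mhc and Act57B unbound. The calls of the segmentation and muscle lists ended when genes with a divergent neighbour were left out (odds ratio 0.461, exact adjusted p = 0.155, and odds ratio 0.143, exact adjusted p = 0.0543). They also ended with the nearest TSS only (odds ratio 0.384, exact adjusted p = 0.0617, and odds ratio 0.371, exact adjusted p = 0.173). Of 14 alternatives the segmentation call ended in 3, and the muscle call ended in 3 and turned in 1. Among the 1000 strongest peaks the segmentation call ended (odds ratio 0.170, exact adjusted p = 0.150) and the muscle odds ratio turned to 1.24 (exact adjusted p = 0.762).

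Testis-specific, neuronal differentiation and apoptosis genes did not pass the test. Testis-specific genes were bound at 6 of 27 (22.2%, odds ratio 0.416, exact adjusted p = 0.0586), and with the larger thresholded list they did pass as bound less often (odds ratio 0.362, 0.146 to 0.897, exact adjusted p = 0.0371), while with replicate 1's list the odds ratio was 0.694 (exact adjusted p = 0.572). They were led by mia (1266), Arp53D (1016), achi (586) and Cyt-c-d (561), with dj and djl unbound. Neuronal differentiation genes were bound at 7 of 24 (29.2%, odds ratio 0.600, exact adjusted p = 0.302), and only 2 of the 7 were bound in both replicates. With the list of replicate 1 and with a TSS window of 250 bp this list did pass as bound less often (odds ratio 0.180, exact adjusted p = 0.0103, and odds ratio 0.162, exact adjusted p = 0.00614). Nrg (1968) and elav (634) had the highest values, nSyb (123) and brp (99.0) were not bound in replicate 1, and Syt1 and Syx1A were unbound. Apoptosis genes were bound at 8 of 14 (57.1%, odds ratio 1.95, exact adjusted p = 0.293), with Dcp-1 (1584), Buffy (1235), Diap1 (903) and Drice (196) highest and the death activators rpr and grim unbound. None of the 111 replication-dependent histone genes was bound (exact adjusted p = 5.52e-25), but none had a ranked entry either, so these repeated genes could not be assessed. All list tests were Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over the 18 lists.

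**Figure D1:**
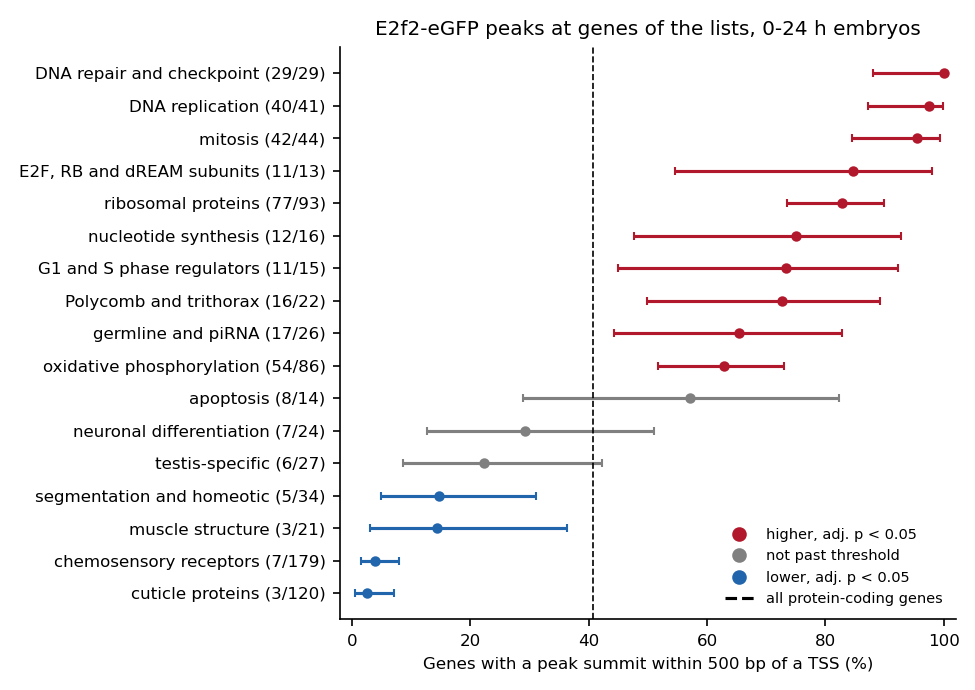
Percentage of genes in each list that carried a main-list peak summit within 500 bp of a TSS (x axis), with exact 95% intervals over genes; each line is a list with its bound and total genes, without the histones, and the dashed line is the share of all 13968 protein-coding genes (40.7%). DNA repair, DNA replication and mitosis genes lie at the top, between 95.5% and 100%, and chemosensory receptor and cuticle protein genes at the bottom.

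Genes arranged head to head with a neighbour were bound more often than other genes. Of 4650 genes with an oppositely oriented neighbour TSS within 1000 bp upstream, 3083 were bound (66.3%), against 2598 of 9318 others (27.9%; odds ratio 5.09, 4.72 to 5.49, Fisher's exact test, two-sided). Rbf2, Skp2, PolE2 and Gpdh1 were bound genes of this kind. A peak between such genes counts for both, and when each peak was assigned to its nearest TSS alone the odds ratio was 1.94 (1.80 to 2.09). Among the 1000 strongest peaks it was 1.33 (1.17 to 1.51).

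By chromosome, X-linked genes were bound slightly more often than autosomal genes (977 of 2196, 44.5%, against 4687 of 11669, 40.2%; odds ratio 1.19, 1.09 to 1.31, exact adjusted p = 2.52e-04). This direction turned among the 1000 strongest peaks, which fell at X-linked genes less often (odds ratio 0.526, 0.427 to 0.648, exact adjusted p = 3.04e-10), and against genes with a stronger ranked entry the call ended (odds ratio 1.11, exact adjusted p = 0.114). Genes on the small chromosome 4 were bound less often (17 of 80, 21.3%, odds ratio 0.402, 0.235 to 0.688, exact adjusted p = 5.13e-04), and none of the 23 genes on Y was bound (exact adjusted p = 3.68e-05), but none had a ranked entry either, so Y could not be assessed. Against genes with a stronger ranked entry the call of chromosome 4 ended as well (odds ratio 0.517, 0.268 to 0.996, exact adjusted p = 0.114). These were Fisher's exact tests, adjusted over the 3 comparisons.

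Over the whole main list, peak summits were enriched for the E2F motif and, more so, for motifs of housekeeping promoters. The E2F motif TTTSSCGC (S is C or G) was present within 100 bp of 577 of 7312 summits (7.89%), against 3.91% of windows centred 500 bp away (difference 3.98 percentage points, 3.22 to 4.74, exact McNemar test, exact adjusted p = 3.32e-24). The same string reversed, a control of equal composition, was at 2.63% against 2.19% (0.438 points, -0.0623 to 0.938, exact adjusted p = 0.0964), although it did pass the test in 8 of its 12 alternatives. DRE (TATCGATA), the element bound by the factor DREF, was at 10.2% of summits against 0.684% of flanks, and Motif 1, the element bound by M1BP, at 5.69% against 0.328% (exact adjusted p = 5.64e-160 and 9.70e-94). CHR (TTYGAA), a short element of mammalian cell cycle promoters, was at 45.8% against 23.1% (exact adjusted p = 6.12e-179), and its reversed string AAGYTT, tested after the result was seen, also rose, from 18.8% to 29.5%. The reversed strings of DRE (0.711% against 0.274%, exact adjusted p = 2.08e-04) and of Motif 1 (0.903% against 0.0821%, exact adjusted p = 1.09e-13), tested at the same time, were higher at summits too. The Myb motif YAACKG was at 29.8% against 27.7% (exact adjusted p = 0.00573). Its call ended among the 1000 strongest peaks (3.4 points, -0.611 to 7.41, exact adjusted p = 0.123). Zelda sites (CAGGTAR), bound by the activator of the early embryonic genome, were lower at summits (2.20% against 3.13%, exact adjusted p = 8.52e-04), and GAGA elements did not differ past the threshold (2.84% against 3.38%, exact adjusted p = 0.0796), although of 12 alternatives they passed as lower in 5 and as higher in 1.

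Against ranked candidates at a TSS that did not pass the threshold, the E2F motif was again more frequent at peaks (8.82% of 5148 against 4.72% of 10508, odds ratio 1.95, 1.71 to 2.23, Fisher's exact test). DRE had an odds ratio of 10.3 (8.61 to 12.3), Motif 1 9.51 (7.58 to 11.9) and CHR 2.67 (2.49 to 2.86), while Zelda and GAGA had 0.595 (0.476 to 0.745) and 0.421 (0.348 to 0.511). The Myb motif did not differ (odds ratio 1.01, 0.937 to 1.08, exact adjusted p = 0.869), and the reversed E2F string had 1.27 (1.03 to 1.56). At peaks farther than 500 bp from a TSS the excess of the E2F motif over flanks did not pass the test (1.25 points, -0.0669 to 2.56, exact adjusted p = 0.117). The calls of Motif 1 (0.323 points), Zelda and Myb (-1.06 points) ended there as well, and the excess of DRE fell from 9.48 to 1.48 points (0.792 to 2.17) and that of CHR from 22.6 to 13.9 points (11.1 to 16.7).

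**Figure D2:**
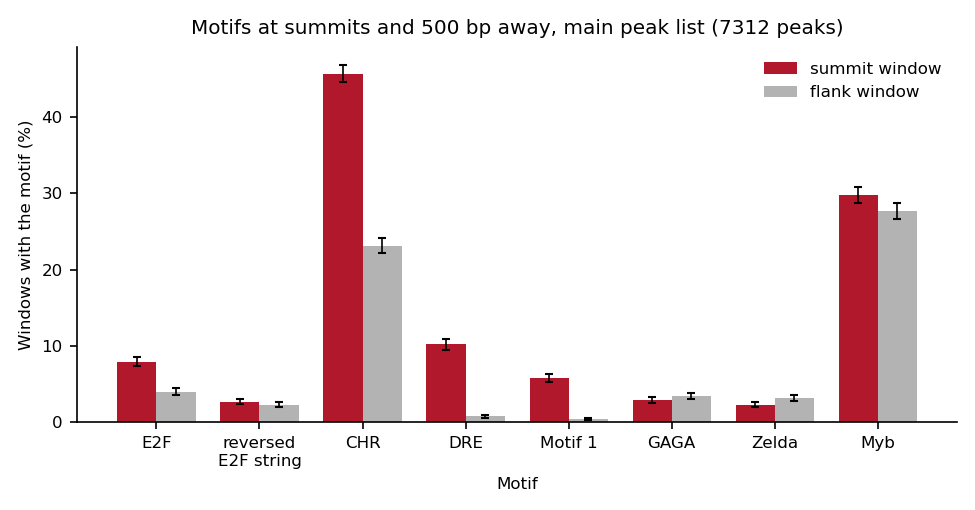
Percentage of windows holding each motif (y axis) at the 7312 main-list summits and 500 bp to a randomly chosen side; windows reach 100 bp either way from their centre, and error bars are exact 95% intervals over windows. E2F rises from 3.91% to 7.89%, DRE from 0.684% to 10.2% and Motif 1 from 0.328% to 5.69%, while the reversed E2F string lies at 2.19% and 2.63%.

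The E2F motif went with strong peaks. Peaks with the motif had a median signal value of 416 (577 peaks), against 168 for the 6735 without it (difference 248, permutation test, two-sided, p = 1e-05, the smallest these permutations can give). The difference was 127 with replicate 1's list and 117 with replicate 2's list. The median signal values of these lists were also lower (87.6 and 106, against 174 in the main list). It was 77.6 with the looser motif WTTSSCSS and 99.1 among the 1000 strongest peaks (permutation p = 0.0188). Among those 1000 the excess over flanks was 16.1 points for E2F, 19.8 for DRE and 8.8 for Motif 1. It was 2.1 points for the reversed E2F string (exact McNemar test, exact adjusted p = 0.0206). The largest was that of CHR, at 44.5 points (40.6 to 48.4), and the reversed string of CHR was not tested there. In the strongest 20% of the list 18.0% of summits had the motif (16.1 to 20.1), against 6.70%, 5.54%, 4.51% and 4.72% in the following steps of 20%. The reversed string was at 4.04%, 2.53%, 1.98%, 1.78% and 2.80% in the same order. DRE fell more steadily, from 18.7% to 3.62%, and the share of summits at a TSS fell from 87.5% to 58.9%. Among bound genes, Ts had the form TTTCCCGC near its summit, and PolE2 had TTTCGCGC.

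**Figure D3:**
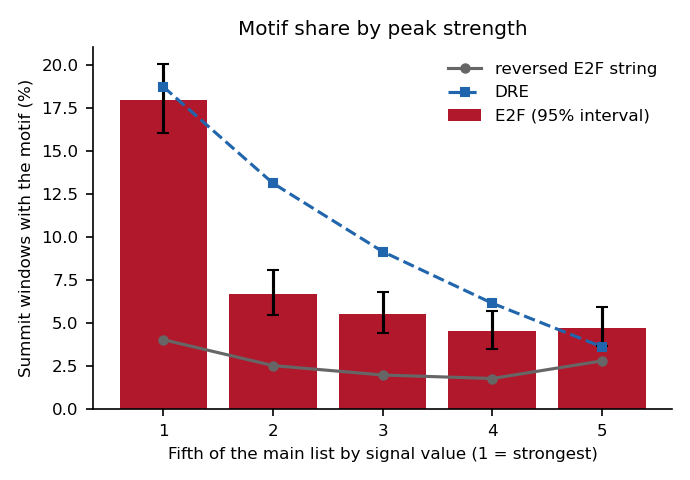
Percentage of summit windows with the E2F motif (bars, exact 95% intervals over peaks), the reversed E2F string and DRE (lines) in 5 equal parts of the main list ordered by signal value (x axis, 1 is strongest). The E2F bar of the strongest part stands at 18.0%, and the others lie between 4.51% and 6.70%.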

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

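The entries described here were looked at only after the lists had been read. The ranked lists hold entries that pass the IDR threshold and are absent from the matching thresholded lists, and these were outside every comparison above. There were 181 such entries for the main list, 209 for the larger list of both replicates, 142 for replicate 1 and 190 for replicate 2, where a list cut at the threshold alone would give 0.

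Most of those absent from the main list were on 3R (114 entries, 6.51% of all that passed there) and 2L (40, 2.94%), against 8 on 2R, 7 on 3L and 6 on X. A further 6 were on other scaffolds, where every passing entry was absent (100%). They were not weak: their median signal value was 199, and the strongest held rank 33 of the ranked list. Of the 175 on chromosome arms, 113 (64.6%) had a summit within 500 bp of a TSS. Of the 138 absent entries of replicate 1 on these arms, 128 overlapped an entry of replicate 2 that passed the threshold, and for 127 of them that entry was absent from the thresholded list of replicate 2 as well. Returning them to the main list raised the number of bound genes from 5681 to 5787, among them ATPsynC, COX7AL2, RpL13A, Syx1A, osa and trx of the gene lists, named here after their values were seen. Of the genes given as unbound above, ATPsynC and Syx1A thus had a passing entry. No explanation was tested.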

How the results depend on the processing

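The alternatives chosen only after the results were seen were a single entry per region, the return of absent entries, the background of genes with a stronger ranked entry, and the nearest TSS. The lists of DNA replication, mitosis, DNA repair, chemosensory receptor and cuticle genes kept their calls in all 14 alternatives, as did the frequent binding of genes with divergent neighbours. With the list of either replicate in place of the main list, 66.4% (lowest) to 78.1% (highest) of summits lay at a TSS, 4680 to 5884 genes were bound, 8 to 10 lists were bound more often and 5 less often (with replicate 1 the muscle list lost its call, odds ratio 0.330, and the neuronal list gained one, 0.180), the E2F excess was 3.72 to 5.70 points, and the odds ratio of X was 1.16 to 1.17. Separate lists of 2 replicates give no more than this range. Each count of lists bound less often in this section, in this paragraph and the next, includes the histone list, which could not be assessed. The lists that could be assessed number 1 fewer each time.

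Among the 1000 strongest peaks 1092 genes were bound, 5 lists were bound more often and 3 less often, the odds ratio of X turned to 0.526, and that of muscle genes turned to 1.24. Lists bound more often numbered 6 against genes with a ranked entry and 5 against genes with a stronger ranked entry, where the odds ratio of X was 1.11 and lost its call, and that of testis-specific genes against genes with a ranked entry turned to 1.10. Lists bound less often numbered 3 without genes that have a divergent neighbour and 3 with the nearest TSS only. The share of replicate 1 peaks found in replicate 2 was 77.8% with 50% reciprocal overlap, 87.3% with summits within 100 bp and 90.5% between the 1000 strongest of each; for replicate 2 the shares were 50.9%, 52.9% and 90.5%. Away from TSSs the E2F excess fell to 1.25 points and lost its call, that of Myb turned to -1.06 and that of the reversed string to -0.185, while windows reaching 200 bp either way turned GAGA to 1.44. The cause of these changes was not tested.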

Other observations

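Of the tests in this part, those of the E2F motif within ranges of distance from a TSS, of the E2F motif at DNA replication genes, of signal values by list and of motifs by list other than CHR at mitosis genes were chosen after the results were seen, as was the background of genes with a stronger ranked entry. Several of the strongest peaks lay outside the promoter window. The peak of rank 2 in the main list (signal value 4277, 2R, 14302489 to 14303193, intergenic) had its summit 505 bp from a TSS of tej, a piRNA pathway gene, just outside the window, and held TTTCCCGC at 14302841. The peaks of rank 3 and 4 were intergenic and lay 3398 bp from slbo, a C/EBP gene needed for border cell migration (3407), and 1655 bp from SmD1, a splicing factor gene (3384). Next came peaks nearest RhoL (2909), CG3505 (2880), CG10651 (2865) and Cipc (2852), and that nearest ush, a GATA cofactor gene, lay in a 5′ UTR 589 bp from its TSS (2659). In all, 2164 main-list peaks were farther than 500 bp from a TSS, 1294 of them (59.8%) in introns, with a median signal value of 126 against 207 at TSSs.

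Some genes that make no protein also had a peak at their 5′ end. Of 290 tRNA genes 27 (9.31%, exact 95% interval 6.23 to 13.3) had a main-list summit within 500 bp of their 5′ end, and 17 of 269 snoRNA genes did (6.32%, 3.72 to 9.93). Of those farther than 1000 bp from a protein-coding TSS, 9 of 211 tRNA genes and 3 of 184 snoRNA genes were bound. Spliceosomal and other snRNA genes were bound at 6 of 32 (18.8%, 7.21 to 36.4), 5 of them among the 27 far from protein-coding TSSs. For comparison, 279 of 3289 genes annotated as ncRNA (8.48%), 21 of 330 pseudogenes (6.36%) and 0 of 99 rRNA genes were bound. Among protein-coding genes the share was 40.7%. Farther than 1000 bp from a protein-coding TSS, 84 of 2353 ncRNA genes and 5 of 248 pseudogenes were bound. The tRNA and snoRNA shares were thus close to those of ncRNA genes and pseudogenes. No share expected from random positions was computed for these classes. No test between these classes, or against protein-coding genes, was run.

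Signal values and motifs at the bound genes of each list were compared with those of all other bound genes, and no list was tested against another. Bound mitosis genes had a median signal value of 822 and bound DNA replication genes 588, against about 250 for other bound genes (250 and 251; differences 572 and 338; permutation tests, adjusted p = 1.00e-04 and 0.00125 over 10 lists). Ribosomal protein genes did not differ (260 against 252, permutation test, adjusted p = 0.796). The E2F motif was near the best summit of 17 of 40 bound DNA replication genes (42.5%) against 8.54% of other bound genes (odds ratio 7.91, 4.20 to 14.9, Fisher's exact test, adjusted p = 7.55e-07 over 68 tests), and of 2 of 42 bound mitosis genes. Mitosis genes had Motif 1 at 12 of 42 (28.6%) against 8.96% (odds ratio 4.07, 2.07 to 7.99, Fisher's exact test, adjusted p = 0.00837). Motif 1 at germline genes (29.4%, odds ratio 4.19) and E2F at neuronal genes (42.9%, odds ratio 7.83) did not pass after adjustment (Fisher's exact test, adjusted p = 0.204 for each). Nor did E2F at DNA repair and checkpoint genes, at 7 of 29 (24.1%) against 8.70% (odds ratio 3.34, 1.42 to 7.85, Fisher's exact test, adjusted p = 0.186). Bound DNA replication genes may thus be set apart by E2F sites, a hypothesis formed and tested on the same data. Whether CHR marks bound mitosis genes was left undecided (57.1% against 49.7%, odds ratio 1.35, 0.732 to 2.49). E2F and DRE motifs neither avoided nor sought each other by a detectable margin at TSS peaks (60 with both, 61.6 by chance, odds ratio 0.968, 0.729 to 1.29).

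The frequent binding of DNA replication and mitosis genes was set against 2 technical explanations, each tested on the DNA replication list. Whether it came from promoters that many factors occupy was left open: among genes with a stronger ranked entry the odds ratio of the DNA replication list was 22.9 (3.15 to 167), but bound genes enter that background through their own peaks, and maps of other factors were not used here. If it came from shared divergent promoters, it should vanish without genes that have a divergent neighbour, where all 16 remaining DNA replication genes were bound (odds ratio 85.9, 5.15 to 1432). For the mitosis list the odds ratio was 24.1 (3.31 to 175) among genes with a stronger ranked entry. Without genes that have a divergent neighbour 16 of 18 mitosis genes were bound (odds ratio 20.8, 4.78 to 90.6). The limit of the first test holds for every other list as well. No biological explanation was tested, since the design has a single group.

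The excess of the E2F motif at summits is unlikely to come from base composition alone, since it exceeded that of the reversed string by 3.54 points (bootstrap 95% interval 2.63 to 4.47). Against candidates in the same range of distance from a TSS the motif was also more frequent at peaks (odds ratio 1.78, 1.55 to 2.05). A like motif content of all TSSs would not give this difference. The reversed string was not compared within these ranges. Over all distances it was more frequent at TSS peaks too (odds ratio 1.27, 1.03 to 1.56), so this contrast was not controlled for base composition. Away from TSSs the excess of 1.25 points (-0.0669 to 2.56) leaves open whether E2f2 peaks there are marked by the motif, and the difference from the excess at TSSs was 3.88 points (2.27 to 5.49). No biological explanation was tested.

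Replicate 2 had more peaks than replicate 1, and lower enrichment or depth in replicate 1 is a candidate explanation. Of the 3154 peaks found in replicate 2 alone, 91.9% (90.9 to 92.9) had a ranked entry in replicate 1 below its threshold or removed. Of the entries of replicate 2 below the threshold, 52.6% had any ranked entry in replicate 1, thresholded ones included. Thresholded peaks of replicate 2 had a median signal value of 106, against 12.8 over its ranked list. Stronger peaks may be ranked more often whatever the cause, so this contrast cannot decide for that explanation. The peaks of replicate 2 alone also stood low in their own list, at a median percentile of 26.7. Read depths were not given in the sources used here, so depth and enrichment cannot be separated, and no biological difference between the replicates is named by the labels.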
